A study of Mus musculus with 3 samples.

How the data were processed

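RNA from 3 sorted populations of differentiated mouse embryonic stem cells, with 1 library each, was analysed from the values the authors deposited. Per the labels' protocols, RNA was prepared from sorted cells with a small-sample kit, libraries were made with a TruSeq RNA kit and sequenced as single reads of 50 bases on a HiSeq2500. Per the submitters' processing notes, FastQC 0.11.2, STAR 2.3.0e, bedtools 2.17.0 and DESeq2 1.2.10 were used with the mouse genome build mm10, and the role of each tool is not given in the sources used here. The deposited table holds 1 signal value per gene and library, a read count divided by 1 size factor per library, for 39179 Ensembl genes with their chromosome, start, end, symbol and biotype. All 3 value columns were matched to the labelled populations by name. Coordinates are those of the table.

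Each library's values were whole multiples of a single step, the value of 1 read, which was 0.914 in GFP, 1.01 in MHC and 1.13 in NEG. Divided by that step, 100% of the values in each library came out whole within a tolerance of 0.01. The recovered reads numbered 52109065 in GFP, 52826956 in MHC and 47289405 in NEG, over 30862, 30825 and 30330 genes with at least 1 read. A read overlapping several genes adds to each of them, so these totals are sums over genes. The 10 genes with the most reads held 7.70% of the total in GFP, 15.6% in MHC and 16.9% in NEG, and the type I collagen genes Col1a1 and Col1a2 together 2.00%, 8.53% and 8.86%. The table has 37 genes of the mitochondrial chromosome and 255 genes on patches and unplaced contigs, all with 0 reads in every library.

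The positions of the table were set against GENCODE M21. Of its genes, 37607 were found there by identifier, 70.2% of them with identical coordinates and 99.7% with an overlapping position. Among 1015 genes of 300 or more reads that lie inside an intron of a host gene, the host's count was at or above the nested gene's in 100%, and the same held for 100% of the 577 on the opposite strand. Reads were therefore treated as counted over the whole gene span, introns included, on both strands and into each overlapping gene. Of 22235 genes with a mean of 10 or more, 7860 (35.3%) are overlapped by a gene with at least 25% of their reads. Such genes are called uncertain where they are named, since the table does not separate the partners.

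Ratios were computed on the log2(value + 1) scale, which understates the differences of low genes, and folds are ratios of the deposited values. A gene counted as differing at 2-fold or more on that scale with a value of 20 or more in the higher library, a rule of size and not a test. With 1 library per population there are no residual degrees of freedom, so no count model was fitted to the recovered reads, no genes are called by one, and no p-value is given. Exact 95% intervals of a ratio (Clopper-Pearson, conditional binomial on the recovered reads) describe the libraries, not the populations. Reads without molecular identifiers are not independent molecules, so intervals and lower limits cover counting error only. For a gene with 0 reads in a library, the lower limit of the fold was set against 3 reads in that library, a value of 2.74 in GFP, 3.04 in MHC and 3.39 in NEG.

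Before the data were examined, 29 gene lists with 483 entries were fixed, all found in the table. They hold the sort reporters, Purkinje and fast conduction, nodal and pacemaker, sarcomere, calcium handling, cardiac transcription factors, atrial, ventricular, potassium channel and metabolism genes. Markers of other cell types are neuronal, glia and neural crest, fibroblast and matrix, smooth muscle, endothelial, epicardial and mesothelial, haematopoietic, endoderm and hepatic, epithelial, pluripotency and skeletal muscle genes. The remaining lists are cell cycle, cAMP, nitric oxide and cGMP, Notch, neuregulin and endothelin, stress, housekeeping and mitochondrially encoded genes. Some genes stand in several lists. A member was measured with a mean of 10 or more over the 3 libraries. A list's median was set among 10000 random lists of the same size matched on mean expression in 20 bins, and it stood apart in either outer 2.5% of these (250 lists), which describes these libraries and is no p-value. Lists under 5 measured members got no percentile. The rule for named genes, fixed at the same time, took the 10 highest and 10 lowest ratios of each pair and the 10 leading genes of each population among genes with a value of 100 or more, without predicted gene models and small RNAs. It also took up to 4 members of each list by mean and 2 in each direction by ratio, and every Purkinje and reporter gene. Genes named outside it are said to have been chosen after their values were seen. A few list members count in the list results but are not reported here by name.

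The computation was tested on simulated reads drawn from the libraries' means for 39179 genes, with 100 genes changed 4-fold and 100 changed 3-fold in each pair. For GFP over MHC it recovered 100% of both, for GFP over NEG 100% of the 4-fold and 99% of the 3-fold genes, and for MHC over NEG 99% and 100%. Of unchanged genes, 0.132%, 0.152% and 0.163% were called in these pairs, and the intervals covered the true ratio of unchanged genes in 95.5%, 95.1% and 95.6%. For changed genes, coverage ran from 92% for 4-fold genes in MHC over NEG to 98% for 3-fold genes in GFP over MHC. The simulated reads carried counting error only, so these shares are no error rate for genes that differed between the real libraries. Of 200 simulated lists of 15 genes with no shift, 6.5% stood apart for GFP over MHC, 2% for GFP over NEG and 4% for MHC over NEG, and with a shift of 0.5 on the log2 scale 100% did in each pair. Random lists of the real libraries spread more widely, for 15 measured nodal and pacemaker genes from −0.54 to 0.60 in GFP over MHC. A shift of 0.5 lies inside that range, so the 100% does not carry over to such lists.

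Alternatives planned at the outset were other pseudocounts, other minimum values or none, 4-fold in place of 2-fold, a higher mean for list members, an interval that excludes 1, and scaling to the same total, by TMM or by the median ratio. Those added after seeing the data left out genes overlapped by others, kept protein-coding genes only, or left out Cntn2 and Myh6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 only for the TMM factors. Spread between replicates could not be estimated.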

Results

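RNA was sequenced from mouse embryonic stem cells that had been differentiated in culture and then separated by fluorescence-activated cell sorting. The cells carried an eGFP reporter for Cntn2 (contactin 2), a cell adhesion gene used as a marker of cardiac Purkinje cells, and a lentiviral mCherry reporter driven by the promoter of Myh6 (the alpha myosin heavy chain of heart muscle, called αMHC in the labels). Sodium nitroprusside, a nitric oxide donor, was given from day 4, and the cells were sorted on day 25. The 3 populations were cells negative for both reporters (NEG), cells positive for mCherry (MHC) and cells positive for eGFP with dim mCherry (GFP). Each population had 1 library, so no difference below has a replicate check and no p-value is given. Whole reads recovered from the deposited values numbered 52109065 in GFP, 52826956 in MHC and 47289405 in NEG. Values are size-factor-normalised read counts per gene, and 95% intervals and lower limits cover counting error only.

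Of the genes behind the reporters, Cntn2 was highest in GFP and Myh6 in MHC, which checks the labels and is not a finding. Cntn2 (ENSMUSG00000053024, chr1:132509425-132542940, mm10, protein-coding) had a value of 10045 in GFP, 228 in MHC and 204 in NEG, 44.1-fold (95% interval 38.6 to 50.5) higher in GFP than in MHC. Myh6 (ENSMUSG00000040752, chr14:54941921-54966927, protein-coding) had a value of 4694 in GFP, 186924 in MHC and 3843 in NEG, 39.8-fold (95% interval 38.7 to 41.0) higher in MHC than in GFP. In GFP, labelled as dim for mCherry, Myh6 was 1.22-fold (95% interval 1.17 to 1.28) its level in NEG and so within 2-fold of it.

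GFP was first set against MHC, which asks how Cntn2:eGFP-positive cells differed from mCherry-positive cells, with Purkinje and fast conduction genes as the main interest. Of 22 measured members of that list, 4 were at least 2-fold higher in GFP, 12 were at least 2-fold lower and 6 lay within 2-fold (median −1.31, below 10000 of 10000 random lists). The median was −0.66 without genes that overlap others, and still below the random range. Members count as higher or lower only with a value of 20 or more in the higher library. List medians here and below are of log2 ratios, and the random lists are matched on mean expression. The 4 higher members were Cntn2, whose reporter defined the sort, the T-type calcium channel gene Cacna1g, the connexin 40 gene Gja5 and the natriuretic peptide clearance receptor gene Npr3. Cacna1g (ENSMUSG00000020866, chr11:94408391-94474198) had a value of 6217 in GFP, 1210.4 in MHC and 788 in NEG, 5.14-fold (95% interval 4.83 to 5.47) higher in GFP than in MHC. Gja5 (ENSMUSG00000057123, chr3:97032416-97053634), whose protein couples fast-conducting cells, was 3.70-fold (95% interval 1.82 to 8.28) higher at a low level, with 41 reads in GFP, 10 in MHC and 0 in NEG. Npr3 was 3.45-fold (95% interval 3.06 to 3.89) higher.

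Transcription factors and channels of fast conduction were among the lower members. Irx5 (ENSMUSG00000031737, chr8:92357796-92361456) was 20.1-fold (95% interval 14.9 to 27.7) lower in GFP than in MHC, and Irx3, a regulator of His-Purkinje conduction, was 17.0-fold (95% interval 13.4 to 21.9) lower. Both were highest in the double negative cells, so their levels did not follow the heart muscle reporter. Irx5 had a value of 42.0 in GFP, 846 in MHC and 4341 in NEG, and Irx3 64.9, 1103 and 1742. The transcription factor gene Nkx2-5, needed for Purkinje fibre development, was 5.84-fold (95% interval 3.82 to 9.26) lower. Among the others, Nppa, Kcnk3, Hopx, Pcp4, Cacna1h, Kcnj3, Tbx5 and Etv1 were lower as well, by 2.27-fold for Etv1 to 12.9-fold for Nppa. Id2, Slit2, Ryr3, Cpne5, Kcnj5 and Ntm lay within 2-fold, and Kcne1 and Scn10a were below the level counted as measured. Irx3, Nppa, Hopx, Pcp4 and Kcnj3 share reads with overlapping genes and are uncertain. Of the lower members, Nkx2-5, Tbx5 and Hopx also stand in the cardiac transcription factor list, Nppa in the atrial list and Kcnk3 and Kcnj3 in the potassium channel list. Their lower levels are thus not particular to fast conduction genes. In the same contrast, epicardial and mesothelial markers had a median log2 ratio of 4.25.

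**Figure D1:**
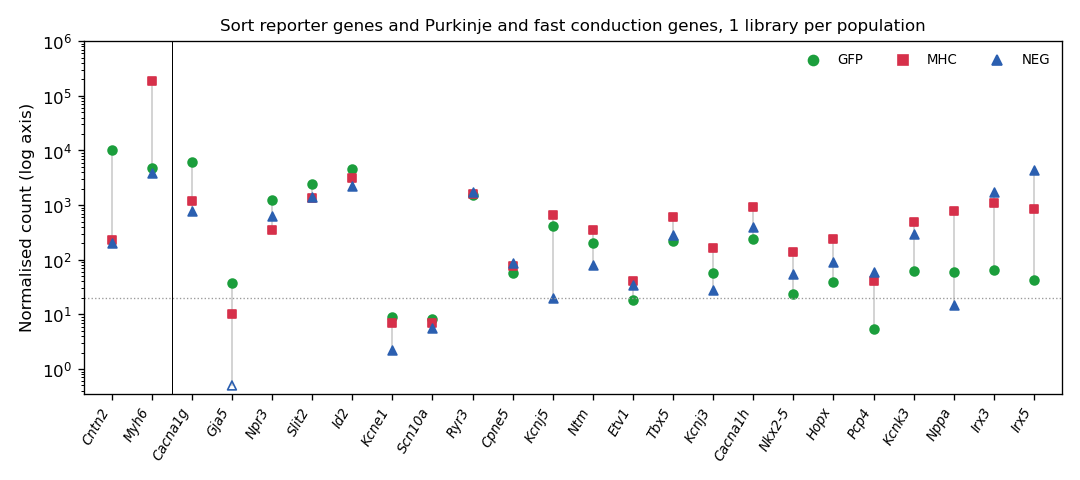
Size-factor-normalised read count (log axis) of the sort reporter genes Cntn2 and Myh6 and of the genes of the Purkinje and fast conduction list named in the text, with 1 point per library for GFP, MHC and NEG, no error bars since each population had 1 library, and a dotted line at 20. The open symbol stands for a value of 0 and is drawn at the bottom of the axis, and Cacna1g and Gja5 have their highest point in GFP while Irx3 and Irx5 have their lowest there.

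Heart muscle genes were lower in GFP than in MHC. Among 26 measured sarcomere genes, 22 were lower and 0 were higher (median −2.87, below 10000 of 10000 random lists). The cardiac troponin I gene Tnni3 was 25.8-fold (95% interval 23.3 to 28.6) lower, the myosin heavy chain gene Myh7 22.3-fold (95% interval 21.6 to 23.1) lower and the troponin T gene Tnnt2 5.56-fold (95% interval 5.37 to 5.75) lower. Cryab and Myl4 lay within 2-fold. For calcium handling, 10 of 15 genes were lower and 0 higher (median −1.98, below 10000 of 10000 random lists). The sarcoplasmic calcium pump gene Atp2a2 was 4.06-fold (95% interval 3.98 to 4.13) lower and the calcium release channel gene Ryr2 14.9-fold (95% interval 12.8 to 17.3) lower. Potassium channel genes were lower for 10 and higher for 2 of 18 (median −1.59, below 10000 of 10000 random lists). Kcnh2, the gene of the rapid delayed rectifier, was 5.69-fold (95% interval 5.02 to 6.47) lower. Genes of fatty acid and respiratory metabolism were lower for 10 of 20 (median −1.06, below 10000 of 10000 random lists). The muscle cytochrome oxidase subunit gene Cox7a1 was 5.28-fold (95% interval 4.20 to 6.68) lower. Cardiac transcription factor genes were lower for 9 of 15 (median −1.48, below 9999 of 10000 random lists), while Gata6 was 4.32-fold (95% interval 4.15 to 4.49) higher in GFP. Atrial genes (2 of 11 higher, 6 lower and 3 within 2-fold, median −1.04, below 9980 of 10000 random lists) were lower as a list. So were ventricular genes (1 of 10 higher, 6 lower and 3 within 2-fold, median −1.66, below 9998 of 10000 random lists). Myh7 shares reads with an overlapping gene and is uncertain.

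The nodal and pacemaker genes went both ways between GFP and MHC, with the pacemaker channel gene Hcn4 higher in GFP. Hcn4 (ENSMUSG00000032338, chr9:58823512-58860955) had a value of 6945 in GFP, 1002 in MHC and 311 in NEG, 6.93-fold (95% interval 6.49 to 7.42) higher in GFP than in MHC. Tbx18, Smoc2 and Bmp4 were also higher, by 4.06-fold, 2.95-fold and 2.33-fold. Tbx3, a transcription factor of the conduction system, was 6.77-fold (95% interval 4.09 to 11.8) lower. Over the list, 4 of 15 genes were higher and 7 lower (median −0.995, below 9991 of 10000 random lists). This call was lost among members with a mean of 100 or more (median log2 ratio −0.42) and without genes that overlap others (−0.19).

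Epicardial and mesothelial genes, which mark the outer lining of the heart and of body cavities, were higher in GFP than in MHC for all 11 measured members (median 4.25, above 10000 of 10000 random lists). The uroplakin gene Upk3b (ENSMUSG00000042985, chr5:136038496-136045303) had a value of 54258 in GFP, 995 in MHC and 1368 in NEG, 54.5-fold (95% interval 51.2 to 58.2) higher in GFP than in MHC. Lrrn4 (ENSMUSG00000043110, chr2:132868305-132880891) was 48.0-fold (95% interval 45.1 to 51.1) higher and Upk1b 28.2-fold (95% interval 26.7 to 29.7) higher. Aldh1a2, which encodes a retinoic acid-forming enzyme of the epicardium, was 19.1-fold (95% interval 16.6 to 22.1) higher. The epicardial transcription factor gene Wt1, chosen after its values were seen, had a value of 4433 in GFP, 641 in MHC and 512 in NEG. Epithelial genes were higher for 6 of 10 (median 2.21, above 10000 of 10000 random lists), with a median of 3.53 among members with a mean of 100 or more. The keratin genes Krt8 and Krt18 were 12.0-fold and 13.6-fold higher, whereas Epcam, the common marker of epithelia, had a value of 25.6 in GFP, 15.2 in MHC and 14.7 in NEG. Cell cycle genes were higher for 7 of 24, lower for 0 and within 2-fold for 17 (median 0.67, above 9972 of 10000 random lists). The thymidylate synthase gene Tyms was 7.91-fold (95% interval 6.51 to 9.70) higher.

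Markers of other cell types were mixed between GFP and MHC. Smooth muscle genes were lower in GFP for 7 of 11 (median −2.68, below 10000 of 10000 random lists). The smooth muscle actin gene Acta2 was 17.0-fold (95% interval 16.4 to 17.7) lower and the kinase gene Mylk 5.01-fold (95% interval 4.89 to 5.13) higher. Fibroblast and matrix genes were lower for 8 and higher for 4 of 20 (median −0.67, below 9827 of 10000 random lists). Col1a1, a chain of type I collagen, was 6.38-fold (95% interval 6.36 to 6.40) lower, whereas Pdgfra and Thy1 were 3.19-fold and 7.22-fold higher. Haematopoietic genes were higher for 8 of 10 (median 1.41, above 9997 of 10000 random lists), with 4 members and no percentile at a mean of 100 or more (1.40). The lipopolysaccharide co-receptor gene Cd14 was 8.40-fold (95% interval 7.83 to 9.02) higher, while the leukocyte gene Ptprc, chosen after its values were seen, was at 10.1 in GFP, 4.05 in MHC and 3.39 in NEG. Glia and neural crest genes had 6 measured members, 4 of them higher (median 1.64, above 9964 of 10000 random lists). Without genes that overlap others this median was 0.82 over 4 members, too few for a percentile, as were the 3 with a mean of 100 or more (1.68). Endoderm and hepatic genes were lower for 4 and higher for 2 of 8 (median −1.90, below 9992 of 10000 random lists), with a median of −0.99 at a pseudocount of 10. Too few members were left for a percentile without genes that overlap others (4, −4.51) and with a mean of 100 or more (2, −2.93). Skeletal muscle genes were lower for 6 and higher for 2 of 11 (median −1.02, below 9959 of 10000 random lists). This call was lost without genes that overlap others (−0.02) and among members with a mean of 100 or more (−0.43). Neuronal genes (6 of 24 higher, 5 lower and 13 within 2-fold, median log2 ratio −0.21) and endothelial genes (4 of 11 higher, 4 lower and 3 within 2-fold, −0.18) did not stand apart from random lists, although the neuronal list was lower among members with a mean of 100 or more (−0.70). The neuronal RNA-binding protein gene Elavl2 was 49.4-fold (95% interval 31.1 to 83.7) higher and Flt1, a receptor for vascular endothelial growth factor, was 58.9-fold (95% interval 43.8 to 81.3) lower.

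Signalling genes related to the culture treatment were also compared between GFP and MHC, since the series title concerns cAMP signalling and nitroprusside is a nitric oxide donor. All populations were treated from day 4, so these comparisons cannot show an effect of the treatment. The cAMP list did not stand apart (3 of 30 higher, 8 lower and 19 within 2-fold, median log2 ratio −0.18). Without genes that overlap others it stood apart as lower in GFP (−0.36). The adenylate cyclase gene Adcy1 was 4.50-fold (95% interval 4.20 to 4.83) higher and Adcy5 13.8-fold (95% interval 12.0 to 15.8) lower. The nitric oxide and cGMP list did not stand apart (4 of 14 higher, 5 lower and 5 within 2-fold, −0.17). Pde5a, the cGMP phosphodiesterase gene, was 3.76-fold (95% interval 3.37 to 4.19) higher and the soluble guanylate cyclase gene Gucy1b3 4.48-fold (95% interval 3.47 to 5.83) lower. Over members with a mean of 100 or more its median was 0.84, above the random range. Notch genes were lower for 8 and higher for 2 of 15 (median −1.45, below 10000 of 10000 random lists). Their median was −0.72, still below the random range, both among members with a mean of 100 or more and without genes that overlap others. The target genes Hes1 and Hey1 were 19.9-fold (95% interval 14.9 to 27.0) and 36.6-fold (95% interval 22.0 to 66.0) lower. Neuregulin and endothelin genes were split (4 of 9 higher, 4 lower and 1 within 2-fold, 0.15). Nrg1, the gene of a growth factor for ErbB receptors, was 19.2-fold (95% interval 17.4 to 21.3) higher and the endothelin receptor gene Ednrb 4.40-fold (95% interval 3.77 to 5.16) lower. Without genes that overlap others the neuregulin and endothelin median was 1.48, above the random range. Stress and immediate early genes (1 of 15 higher, 5 lower and 9 within 2-fold, 0.00) and housekeeping genes (1 of 15 higher, 4 lower and 10 within 2-fold, −0.01) did not stand apart. The glycolytic gene Pgk1 was 7.66-fold (95% interval 7.42 to 7.91) lower in GFP.

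Over all genes, 6668 of 20879 (31.9%) with a value of 20 or more in the higher library differed at least 2-fold between GFP and MHC, 3253 higher and 3415 lower in GFP. By log2(value + 1) ratio, the highest in GFP included the steroid dehydrogenase gene Akr1c18 (ENSMUSG00000021214, chr13:4132615-4150654) at 446-fold (95% interval 152 to 2164) and the prokineticin receptor gene Prokr2 (ENSMUSG00000050558, chr2:132337733-132385447) at 309-fold (95% interval 202 to 499). They also included Lrrtm1 at 349-fold, the growth factor gene Fgf8 at 152-fold and the sodium channel subunit gene Scn3b at 127-fold. Akr1c18 and Lrrtm1 had 3 reads each in MHC, and Lrrtm1 had an interval of 119 to 1693. Dmrt2 had 0 reads in MHC and was at least 44.5-fold higher in GFP, and Ano5, Tm4sf5, Brinp2 and Vnn1 completed the 10 highest. The lowest in GFP were the dipeptidase gene Dpep1, 1139-fold (95% interval 879 to 1504) lower, and Bpifb1, 882-fold (95% interval 344 to 3237) lower. The bone matrix gene Mepe, at 1 read in GFP, was 1311-fold (95% interval 235 to 51822) lower and the collagenase gene Mmp13 472-fold (95% interval 324 to 717) lower. Serpina5, at 0 reads in GFP, was at least 112-fold lower, and Esm1, Crispld2, Gzmk, Podnl1 and Chia made up the rest. Lrrtm1, Dpep1, Crispld2, Esm1 and Gzmk share reads with overlapping genes and are uncertain.

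GFP was next set against NEG, to ask what separated the Cntn2:eGFP-positive cells from cells without either reporter. Epicardial and mesothelial genes were again higher for all 11 (median 3.82, above 10000 of 10000 random lists). Upk3b was 39.7-fold (95% interval 37.5 to 42.0) and Lrrn4 41.6-fold (95% interval 39.1 to 44.3) higher. Sarcomere genes were higher in GFP for 10, lower for 1 and within 2-fold for 15 of 26 (median 0.88, above 10000 of 10000 random lists). The ventricular light chain gene Myl2 was 10.4-fold (95% interval 6.43 to 17.8) higher and the myosin-binding protein gene Mybpc3 6.79-fold (95% interval 5.63 to 8.24) higher, while Myom1, which shares reads with an overlapping gene and is uncertain, was 11.5-fold (95% interval 10.3 to 12.9) lower. Atrial genes were higher for 6 and lower for 2 of 11 (median 1.01, above 9984 of 10000 random lists). Myl7 was 3.69-fold (95% interval 3.06 to 4.49) higher. Ventricular genes (4 of 10 higher, 2 lower and 4 counted as neither, median 0.79, above 9906 of 10000 random lists) lost their call among members with a mean of 100 or more and without genes that overlap others (0.47 in both).

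Purkinje and fast conduction genes were mixed between GFP and NEG, with 8 higher, 6 lower and 8 within 2-fold of 22 measured (median 0.33, above 9497 of 10000 random lists), which is inside the random range. The median was 0.80 and above that range both without genes that overlap others and among members with a mean of 100 or more. Gja5, with 0 reads in NEG, was at least 11.1-fold higher, the inward rectifier gene Kcnj5 was 20.3-fold (95% interval 12.7 to 34.6) higher and Cacna1g 7.89-fold (95% interval 7.29 to 8.54) higher. In contrast, Irx5 was 103-fold (95% interval 77.3 to 141) lower and Irx3 26.8-fold (95% interval 21.2 to 34.5) lower. Hcn4 was 22.4-fold (95% interval 19.8 to 25.3) higher. Nodal and pacemaker genes as a list did not stand apart (4 of 15 higher, 4 lower and 7 counted as neither, median 0.32), but did so without genes that overlap others (0.86). Calcium handling (−0.37), cardiac transcription factor (−0.37), potassium channel (−0.09) and metabolism genes (−0.02) did not stand apart by their medians. Casq2, the calcium store protein gene, was 4.18-fold (95% interval 3.20 to 5.53) higher.

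Other gene groups also separated GFP from NEG. Smooth muscle genes were lower in GFP for 6 and higher for 2 of 11 (median −3.44, below 10000 of 10000 random lists). The smooth muscle myosin gene Myh11 was 20.8-fold (95% interval 18.1 to 24.0) lower. Notch genes were lower for 9 and higher for 3 of 15 (median −1.38, below 10000 of 10000 random lists). Hes1 was 24.3-fold (95% interval 18.2 to 33.0) lower. Endothelial genes were lower for 6 and higher for 3 of 11 (median −1.03, below 9960 of 10000 random lists), a call lost without genes that overlap others (−0.78). Higher in GFP were epithelial genes (6 of 10, median 2.34, above 10000 of 10000 random lists, or 3.33 at a mean of 100 or more), haematopoietic genes (7 of 10, median 2.01, above 10000 of 10000 random lists) and cell cycle genes (9 of 24, median 0.77, above 9996 of 10000 random lists). Aurkb, a mitotic kinase gene, was 6.02-fold (95% interval 3.67 to 10.5) higher. Fibroblast and matrix genes (−0.48), skeletal muscle genes (−0.32), nitric oxide and cGMP genes (−0.24) and neuregulin and endothelin genes (−0.26) had medians inside the random range. Fibroblast and matrix genes (−0.76) stood apart among members with a mean of 100 or more, as did nitric oxide and cGMP genes (0.74). Neuregulin and endothelin genes (1.46) stood apart without genes that overlap others, and skeletal muscle genes did so under both settings (1.93 without overlaps and 0.96 at the higher mean). The cAMP (−0.01), neuronal (0.06), glia and neural crest (0.65), endoderm and hepatic (−0.31), stress (0.08) and housekeeping lists (0.14) did not stand apart.

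Between GFP and NEG, 6055 of 20814 genes (29.1%) differed at least 2-fold, 2933 higher and 3122 lower in GFP. Prokr2 was 342-fold (95% interval 214 to 588) higher, Ano5 255-fold (95% interval 109 to 787) higher and the tight junction gene Cldn3 94.9-fold (95% interval 43.4 to 259.6) higher. H2-M2, a class Ib major histocompatibility gene, at 2 reads in NEG, was 95.9-fold (95% interval 26.3 to 796) higher. Lrrtm1, Scn3b, Camkv, Rab19, Tm4sf5 and Rasgrp3 were the others of the 10 highest. Among the lowest in GFP, the bone sialoprotein gene Ibsp was 252-fold (95% interval 243 to 262) lower and Alpl, the gene of a phosphatase needed for bone mineralisation, 182-fold (95% interval 165 to 202) lower. The cartilage collagen gene Col9a1 was 179-fold (95% interval 162 to 199) lower and the cartilage proteoglycan gene Acan 171-fold (95% interval 156 to 188) lower. The others of the 10 lowest were Chad, Col22a1, Frzb, Loxl4, Gdf10 and Dpep1. Chad, Dpep1 and Lrrtm1 share reads with overlapping genes and are uncertain.

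**Figure D2:**
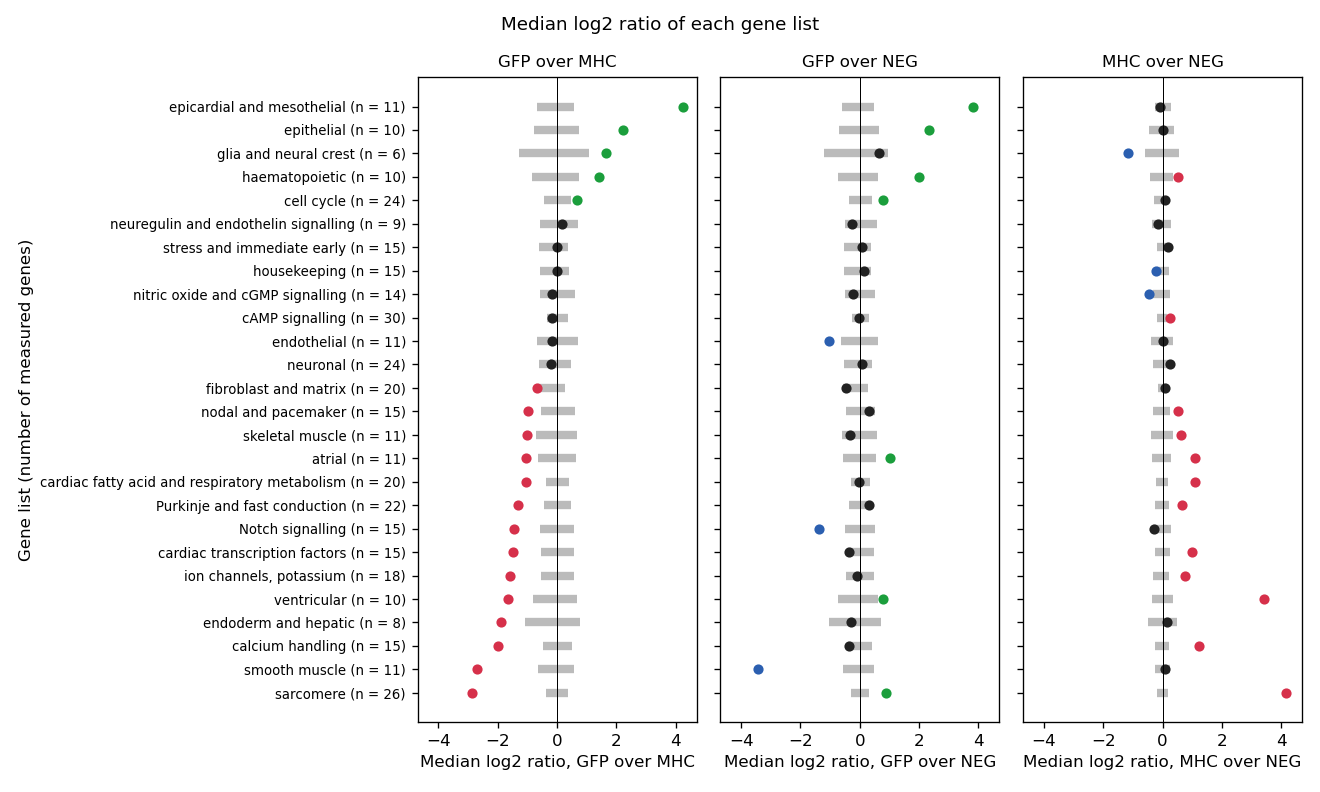
Median log2 ratio of each fixed gene list with 5 or more measured members, for GFP over MHC, GFP over NEG and MHC over NEG. Each population had 1 library. Each point is a median over the number of measured genes given beside the list, grey bars span 95% of the medians of 10000 random lists matched on mean expression, black points lie inside that range, and coloured points lie outside it in the colour of the population with the higher level (green GFP, red MHC, blue NEG). Epicardial and mesothelial genes lie highest for GFP over MHC (4.25) and sarcomere genes for MHC over NEG (4.14).

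MHC was last set against NEG, which shows what the mCherry sort separated. Sarcomere genes were higher in MHC for 23 of 26 and lower for 0 (median 4.14, above 10000 of 10000 random lists). Myh7 was 48.4-fold (95% interval 45.9 to 51.1) higher, Tnni3 46.1-fold (95% interval 39.7 to 53.9) higher and the atrial natriuretic peptide gene Nppa 52.1-fold (95% interval 30.3 to 98.4) higher. Ventricular genes were higher for 7 of 10 (median 3.42, above 10000 of 10000 random lists), with a median of 2.26 at a pseudocount of 10 and 4.04 at a mean of 100 or more, and calcium handling genes for 9 of 15 (median 1.22, above 10000 of 10000 random lists). The same held for atrial genes, with 6 of 11 (median 1.11, above 10000 of 10000 random lists), and metabolism genes, with 11 of 20 (median 1.09, above 10000 of 10000 random lists). Purkinje and fast conduction genes were higher for 9 and lower for 1 of 22 (median 0.66, above 10000 of 10000 random lists). Kcnj5 was 32.2-fold (95% interval 20.2 to 54.6) higher, and Irx5 5.13-fold (95% interval 4.76 to 5.54) lower. Nodal and pacemaker genes (median 0.51, above 9998 of 10000 random lists), cardiac transcription factor genes (median 0.98, above 10000 of 10000 random lists) and potassium channel genes (median 0.77, above 10000 of 10000 random lists) were also higher as lists.

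MHC and NEG were also compared outside heart muscle. Epicardial and mesothelial genes all lay within 2-fold (11 of 11, median log2 ratio −0.07), as did 19 of 20 fibroblast and matrix genes (0.09) and 9 of 11 smooth muscle genes (0.07). Glia and neural crest genes were lower in MHC (0 of 6 higher, 3 lower and 3 within 2-fold, median −1.18, below 9997 of 10000 random lists). Smaller shifts outside the random range were found for nitric oxide and cGMP (−0.46), housekeeping (−0.22), cAMP (0.25), haematopoietic (0.54) and skeletal muscle genes (0.62, or 0.33 and inside the range without genes that overlap others). Neuronal, endothelial, epithelial, endoderm and hepatic, cell cycle, Notch, neuregulin and endothelin, and stress genes did not stand apart, with medians from −0.29 for Notch genes to 0.25 for neuronal genes. Neuronal genes stood apart among members with a mean of 100 or more (0.38) and with a pseudocount of 10 (0.22), and Notch genes did so without genes that overlap others (−0.38). In all, 2172 of 20572 genes (10.6%) differed at least 2-fold, 1101 higher and 1071 lower in MHC. The chitinase gene Chia (ENSMUSG00000062778, chr3:106113229-106132120) was 106-fold (95% interval 55.6 to 232) higher, the sarcomeric gene Lmod2 64.3-fold (95% interval 35.7 to 129) higher and Ckmt2, a mitochondrial creatine kinase gene, 46.0-fold (95% interval 33.4 to 65.2) higher. Zfp42, Nppa, Myh6, Myh7, Tnni3, Mybpc3 and Sln completed the 10 highest. Among the 10 lowest in MHC were C1qtnf3, 33.7-fold (95% interval 14.1 to 105) lower, and the cartilage gene Matn1, 13.8-fold (95% interval 9.31 to 21.3) lower. The others were Itih5l-ps, Pde6h, Hist2h3c2, B4galnt2, Slco2b1, Hs3st6, Cyp4f39 and Fibcd1. Nppa, Myh7 and B4galnt2 share reads with overlapping genes and are uncertain.

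**Figure D3:**
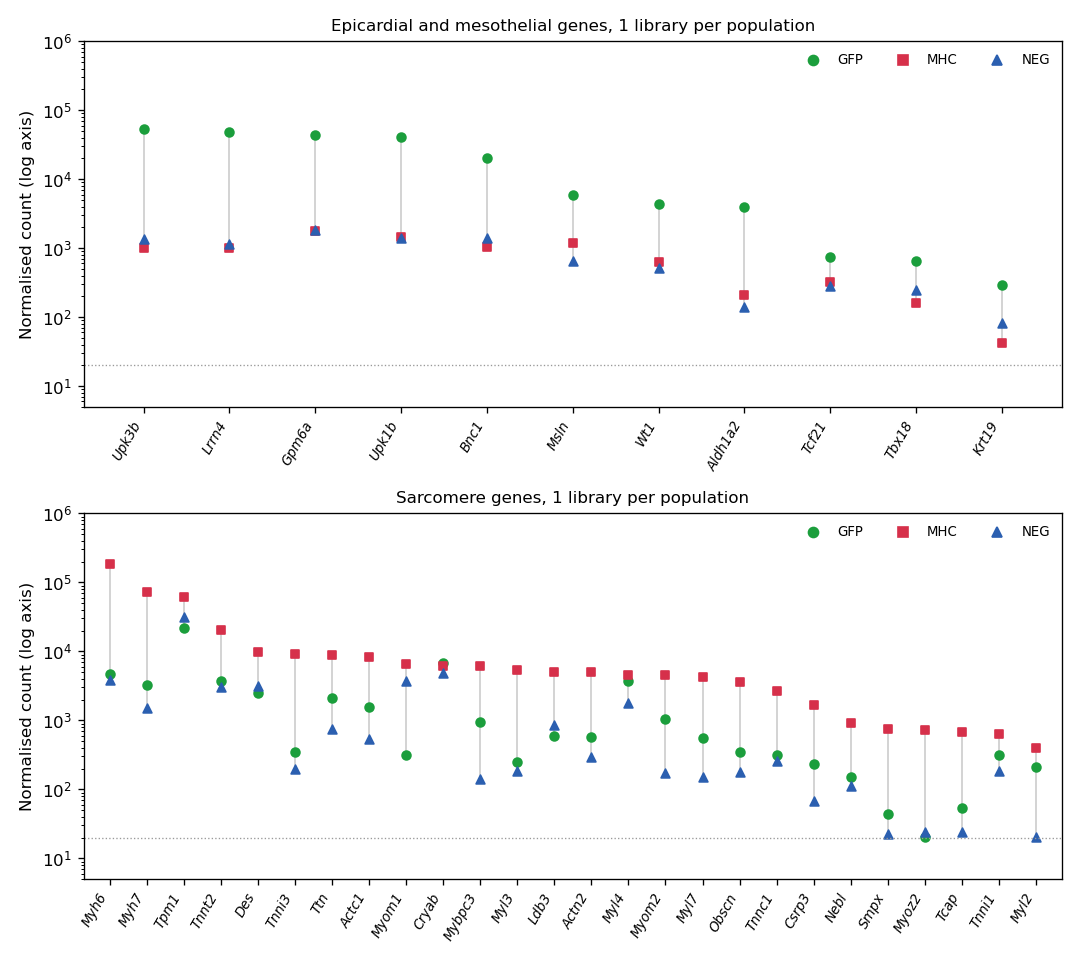
Size-factor-normalised read count (log axis) of each epicardial and mesothelial gene (upper panel) and each sarcomere gene (lower panel), with 1 point per library for GFP, MHC and NEG, no error bars since each population had 1 library, and a dotted line at 20. All 11 epicardial and mesothelial genes have their highest point in GFP, and 22 of 26 sarcomere genes lie at least 2-fold lower in GFP than in MHC.

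Genes at least 2-fold above both other populations numbered 2286 in GFP, 711 in MHC and 577 in NEG. In GFP the leading genes were Prokr2, 309-fold above the higher of the others, Lrrtm1, Ano5, Scn3b, Tm4sf5, Rab19, Akr1c18, the pantetheinase gene Vnn1, the endocytic receptor gene Lrp2 at 60.1-fold, and Camkv. In MHC they were Chia, 106-fold above the higher of the others, Zfp42, Ckmt2, Myh6, Myoz2, Tnni3, the myoglobin gene Mb at 23.9-fold, Tuba8, Myh7 and Trim54. In NEG they were Itih5l-ps, 27.2-fold above the higher of the others, Pde6h, Matn1, B4galnt2, Slco2b1, Hs3st6, Col10a1, Nt5dc1, Avil and Nnat. Col10a1, a collagen of hypertrophic cartilage, had a value of 1224 in GFP, 15087 in MHC and 123637 in NEG, and since Nt5dc1 overlaps it, the same reads were counted in both. Trim54, Avil, Nnat and B4galnt2 are uncertain for the same reason. Among the pluripotency genes, 4 of 14 were measured, too few for a percentile. Pou5f1 and Nanog, chosen after their values were seen, were below the level counted as measured in this list. Zfp42, a gene of pluripotent cells, had a value of 7.31 in GFP, 709 in MHC and 11.3 in NEG. Klf4 (16169.8 in GFP, 6581 in MHC and 8923 in NEG) and Tfcp2l1 (2910.4 in GFP, 641 in MHC and 319.7 in NEG) were higher in GFP than in MHC, and Dppa5a had a value of 21.9 in GFP, 16.2 in MHC and 16.9 in NEG. The 13 mitochondrially encoded genes had 0 reads in every library, so the list could not be measured.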

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

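The alternatives that left out overlapped genes, other biotypes or Cntn2 and Myh6 were chosen after seeing the data. No top-ranked or Purkinje gene with a 2-fold ratio and no list standing apart changed direction under the alternatives run for it. Counts moved over 1.5 times only with the minimum value, the size limit or, for MHC against NEG, overlapped genes left out, each of which by construction admits or removes genes. With no minimum value, 12496 genes differed between GFP and MHC, 11491 between GFP and NEG and 8369 between MHC and NEG, and 3468, 2473 and 2026 were highest in GFP, MHC and NEG. At 4-fold or more the counts were 2805, 2600 and 524 for the pairs and 862, 190 and 139 for the populations. A minimum of 5 gave 4044 genes for MHC against NEG, 1156 highest in MHC and 1006 highest in NEG, and a minimum of 100 gave 1223, 439 and 363. Without overlapped genes, 1424 differed between MHC and NEG. Requiring an interval that excludes 1 left 6647, 6031 and 2150 genes for the pairs.

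Scaling to the same total shifted GFP ratios by 0.17 on the log2 scale against either other library and moved the share of differing genes that were higher in GFP from 48.8% to 57.9% against MHC and from 48.4% to 57.1% against NEG. TMM and median-ratio scaling shifted the pairs by −0.0315 to 0.00802. Of 399 alternative ratios of top-ranked and Purkinje genes, 354 stayed inside the counting interval and 45 moved beyond it. Of 504 alternative list medians, 424 were likewise unmoved and 80 moved, with no called median reversed. Medians standing apart were also checked for moves of over 1.5 times in fold, with their log2 values given here in brackets. At a pseudocount of 10, the movers were endoderm and hepatic genes for GFP over MHC (−0.99) and ventricular genes for MHC over NEG (2.26). Among members with a mean of 100 or more, they were epithelial (3.53), skeletal muscle (−0.43), Notch (−0.72) and endoderm and hepatic genes (−2.93) for GFP over MHC, epithelial genes for GFP over NEG (3.33) and ventricular genes for MHC over NEG (4.04). Without overlapped genes, all were for GFP over MHC: Purkinje and fast conduction (−0.66), nodal and pacemaker (−0.19), glia and neural crest (0.82), endoderm and hepatic (−4.51), skeletal muscle (−0.02) and Notch genes (−0.72). Lists standing apart numbered 19 for GFP over MHC (16 to 19 under the alternatives), 10 for GFP over NEG (10 to 12) and 15 for MHC over NEG (14 to 16). At a mean of 100 or more, or without overlapped genes, some lists fell under 5 measured members, among them glia and neural crest, endoderm and hepatic and haematopoietic genes, and got no percentile. No paired analysis was possible because each population had 1 library, and none could be left out. Depth limits genes of a few reads, whose intervals are wide.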

Other observations

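All tests in this part, and the list of cartilage and bone genes, were chosen after the results were seen. Genes of cartilage and bone were lower in GFP than in NEG and, for most, than in MHC. Of 29 measured genes, 29 were lower in GFP than in NEG (median −6.31, below 10000 of 10000 random lists), 27 were lower in GFP than in MHC (−5.05), and in MHC against NEG 16 were lower, 3 higher and 10 within 2-fold (−1.05). The cartilage collagen gene Col2a1 had a value of 6314 in GFP, 94203 in MHC and 574523 in NEG, and the bone matrix gene Ibsp 2413 in GFP, 293616 in MHC and 608631 in NEG. The list was drawn up partly from genes already seen to be low in GFP, so its medians are not independent of that observation.

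Several secreted, receptor and contractile genes with high levels in GFP also stood out. The complement gene C3, chosen after its values were seen, had a value of 396084 in GFP, 44076 in MHC and 36841 in NEG. Nrg1 had a value of 7855 in GFP, 408 in MHC and 458 in NEG, the natriuretic peptide receptor gene Npr1 4481 in GFP, 206 in MHC and 337 in NEG and the secretogranin gene Scg2 16631 in GFP, 1779.7 in MHC and 3257 in NEG. Npr1 overlaps another gene and is uncertain. Among skeletal muscle genes, the perinatal myosin gene Myh8 was 11.6-fold (95% interval 11 to 12.2) higher in GFP than in MHC and the embryonic myosin gene Myh3 6.38-fold (95% interval 5.27 to 7.79) higher, while the muscle creatine kinase gene Ckm, which overlaps another gene and is uncertain, was 25.2-fold (95% interval 21 to 30.6) lower.

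Epicardial and mesothelial markers were higher in GFP than in both other libraries. The median fold over the higher of the others was 14.2, with 11 of 11 above it (2.28 to 41.6). A mixture of the MHC and NEG populations cannot exceed the higher of them, which follows from the pattern itself and is no further test of it. A lower share of the main cell types would raise markers of other types alike. For GFP over NEG, however, the epicardial median exceeded the smooth muscle median by 7.27 on the log2 scale and the endothelial median by 4.86. These lists, the only ones compared, may not stand for minor cell types, so they cannot decide the question. Only 11 of 17 endothelial members were measured, and Cdh5, chosen after its values were seen, was at 5.48 in GFP and 9.04 in NEG. Acta2 was at 38419 in NEG. Epithelial (2.34) and haematopoietic medians (2.01) did rise, but Krt19 stands in both the epithelial and the epicardial list. Epcam and Ptprc were at 25.6 and 10.1 in GFP, so neither rise shows a separate cell type. Which cell types were the main ones was not tested. A lower share of the main cell types therefore stays open. Reads shared with overlapping genes are argued against because 0 of the 11 members are overlapped by a gene with 25% or more of their reads. What also stays open is that this may be a property of the single library, as there was 1 GFP library, and the sorted population itself, which was not tested further. The values of Upk3b, Lrrn4 and Gpm6a in GFP were 54258, 48158 and 44105. Tbx18, Tcf21 and Krt19 also stand in other lists.

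Over 26 sarcomere and calcium handling genes with a value of 100 or more in MHC and at least 4-fold above NEG there, levels in GFP ran from below NEG to well between NEG and MHC. A random fixed share of MHC cells carried over into the GFP sort would bring their abundant transcripts, and Myh6, the one gene of these with a value of 100000 or more in MHC, allows a share of at most 2.51% whatever the background. In GFP, 10 of 26 genes rose over NEG by more than 2-fold what that share would bring, from 2.25-fold for Actn2 to 18.9-fold for Myl2, which argues against such carry-over as the whole cause for these genes, with 1 library each. For the other 16 it stays open. Among these, Ldb3, Pln, Ryr2 and Myoz2 lay below NEG in GFP, the first 2 beyond counting error, so the background there need not equal NEG. Pln shares reads with an overlapping gene and is uncertain. Reads shared with overlapping genes are argued against by a median log2 ratio of GFP over NEG of 0.94 over the 22 members not overlapped, 19 of them above NEG. A carry-over of selected MHC cells and expression in the GFP cells themselves, described in the labels as dim for mCherry, stay open as well.

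Cartilage and bone genes were also counted in MHC, the population sorted for a heart muscle reporter. A fixed share of NEG cells carried over into the MHC sort would hold each gene at the same share of its NEG level, at most 1. Ratios of MHC over NEG ran from 0.0725 for Matn1 to 7.54 for Spp1, with a median of 0.482, and 3 of 29 genes (Spp1, Mepe and Mmp13) lay at least 2-fold above their NEG level. Carried-over cells bring their abundant transcripts, and Col2a1, the lowest in ratio of the 5 genes not overlapped with a value of 100000 or more in NEG, allows a share of at most 16.4%. The level in MHC was more than 2-fold above what that share would bring for 18 of 29 genes, which argues against a fixed share as the whole cause, with 1 library each. Overlapping genes are argued against by 26 of 26 members not overlapped having a value above 20 in MHC. A carry-over of particular NEG cells could still give such a pattern, as could reporter activity in cells other than heart muscle, and neither was tested.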
